A study of Rattus norvegicus with 19 samples.

How the data were processed

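RNA from 19 rat brains of gestation day 15 (Sprague-Dawley) was measured on Affymetrix Rat Gene 1.0 ST arrays, 1 array per brain. Per the labels, pregnant dams received lipopolysaccharide (LPS, 0.25 mg/kg) or saline vehicle, and the fetal brains were taken 4 h later; 10 arrays were saline and 9 were LPS. Group and replicate number were taken from the sample titles. Dam, litter, fetal sex and array batch are not given in the sources used here, so no term for them was fitted, and p-values measure the spread between these brains rather than between dams.

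The deposited values were on a log2 scale and had been made with RMA (background correction, quantile normalization and summary of probes) in Affymetrix Expression Console, per the submitters' processing notes, which give no versions. No scanner files were used here. The table held 29215 rows, each a transcript with an array identifier. Gene names came from the platform annotation: 15310 rows had 1 gene symbol, 323 had several and 13582 had none, and rows with several or none were tested but not named. Entrez identifiers matched 15279 of the rows with 1 symbol to the RefSeq gene table of the rat assembly GRCr8, and 0 symbols changed. The genome build of the array annotation was not given in the sources used here, so no coordinates are printed. The arrays have no read depth; their number limits the precision, and no background or detection values were analysed here.

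Values were used as deposited. Each row was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with group as the only term, and p was adjusted by the Benjamini-Hochberg method over all 29215 rows; a transcript was called at an adjusted p under 0.05. Fold changes are LPS minus saline on the log2 scale, given with the standard error (SE) of the fit. Before the data were examined, 29 gene lists holding 600 distinct genes were fixed from the tissue and the treatment, and 526 of these genes were measured. The sex chromosome list had too few measured members for a test, which left 28 lists. A gene with several rows was represented by the row with the highest mean over all arrays. Lists were tested with limma camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists, which sets the members of a list against all other genes. Counts of members that rose or fell use the adjustment over all rows, and counts adjusted over the list alone are given beside them. The level of a list in a brain is the mean of its members. Values of single measures were compared with two-sided exact permutation tests over all splits into 10 and 9.

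The genes named in the text were fixed by rule before the data were examined: the 15 rows with the highest and the 15 with the lowest fold change among called rows with 1 symbol, up to 4 called members of each list with the largest change, and, whatever their p, a set of cytokine, interneuron, oxidative stress, metal, hypoxia and glucocorticoid genes. Placeholder symbols (beginning LOC, RGD, MGC, Olr or Vom) and sex chromosome markers were left out of the highest and lowest rows. Npy and Zeb2 lie outside the rule and were named after their values were seen, as the members of their list that rose. Dlx2, a member of the fixed set, is not analysed here.

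The fit and the list test were run on simulated data made from the means and spreads of the real rows, with 200 of the 29215 rows changed. Of rows changed by 1.2-fold, 42 of 67 (62.7%) were called; of those changed by 1.5-fold, 61 of 67 (91.0%); and of those changed by 2-fold, 66 of 66. Of 29015 unchanged rows, 9 were called. The list given a shift was called and 0 others were. The rows were simulated independently of each other, so this does not show how the list test behaves when members of a list correlate. In the real data 14074 rows were called, which makes the adjusted threshold less strict there. The shares recovered and the 9 false calls therefore do not carry over to the real data.

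Alternatives fixed before the data were examined were a minimum mean log2 value of 6, rows with 1 symbol, quantile normalization again, centring each array on its median, trended and robust variance, array weights, exact Wilcoxon rank-sum tests, the replicate number as a block, the erythroid and the meninges level as covariates, other thresholds, leaving out each array in turn, and, for the lists, an estimated correlation, limma fry and the mean of all rows of a gene. Chosen after seeing the data were limma treat at 1.2-fold, leaving out 198 rows with values identical to another row, leaving out LPS replicate 1 with saline replicate 8, an exact permutation test of list levels, and a screen of gene families by shared symbol stem. Y-linked markers were not analysed here, so the planned covariate for fetal sex was not run. Figures were drawn with matplotlib 3.10.9.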

Results

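The brains of 19 rat fetuses at gestation day 15 were compared 4 h after their dams had received saline (10 brains) or lipopolysaccharide (LPS, 9 brains), a component of the bacterial outer membrane that provokes an immune response in the mother without a live infection. The title of the series names interneuron migration, oxidative stress and a fetal immune response as the matters of interest. The median log2 signal was 6.99 ± 0.025 in saline arrays (SD, n = 10) and 6.94 ± 0.024 in LPS arrays (SD, n = 9; exact permutation p = 0.00029). The SD over the transcripts of an array was 2.16 ± 0.023 log2 units in saline and 2.20 ± 0.013 in LPS arrays (exact permutation p = 9.7e-05), so the signal distributions differed between the groups. The leading principal component held 42.5% of the variance and put every saline brain between -27.0 and -12.5 and every LPS brain between 5.66 and 33.0 (exact permutation p = 1.1e-05, the smallest these splits can give). No arrays were duplicates, since the SD of the difference between any pair was at least 0.168.

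**Figure D1:**
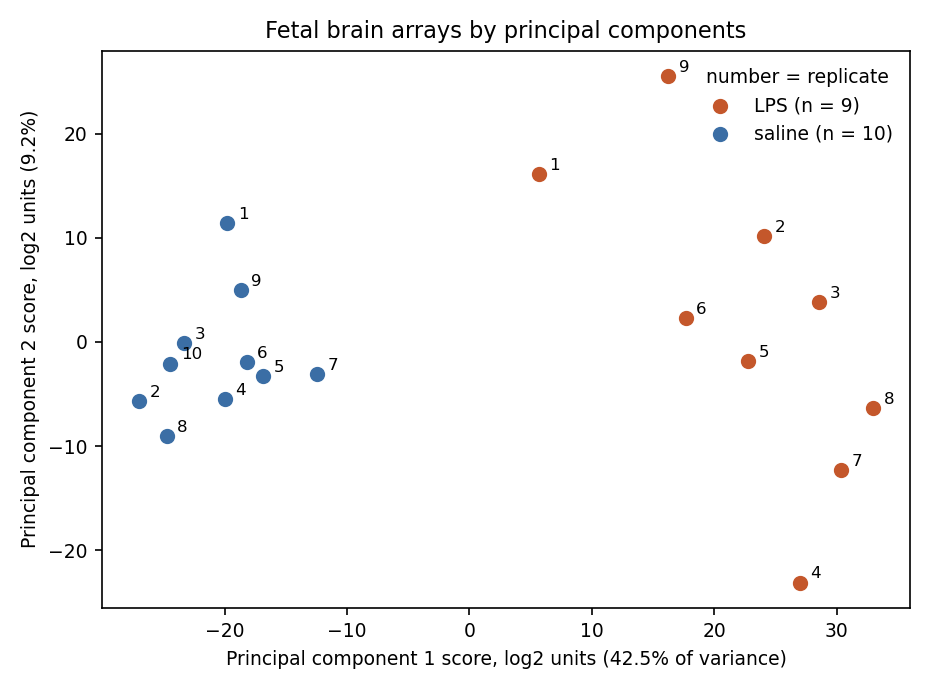
Scores of the 19 fetal brain arrays on the leading principal components of the log2 signal, with saline in blue (n = 10), LPS in orange (n = 9) and replicate numbers beside the points. The groups do not overlap on component 1, which holds 42.5% of the variance.

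The fetal brain transcriptome differed broadly but by small amounts between the groups. Among rows open to naming by the rule, Apold1, an early response gene of endothelium, rose most (log2 fold change 1.55 ± 0.17 SE, 2.92-fold). Next were the red cell genes Ahsp (1.47 ± 0.23), Rhag (1.26 ± 0.20) and Hbg1 (1.21 ± 0.19) and the arrestin domain gene Arrdc3 (1.31 ± 0.16). Bnip3, a mitophagy receptor induced by low oxygen, followed (1.19 ± 0.097, with 1.17 in a further row). Chm, which encodes a Rab escort protein, rose by 1.15 ± 0.069, Cav1, the caveolin of membrane pits, by 1.07 ± 0.10, and Tank, an adaptor of NF-kB signalling, by 1.05 ± 0.072. Also among the highest rows were Lrrcc1 (1.15), Rbm41 (1.11), Mgat4c (1.07) and Zfp867 (1.07). The strongest fall of a named row was in Vof16, from 10.8 ± 0.15 (SD, n = 10) to 8.94 ± 1.33 (SD, n = 9), with LPS brains spread from 7.15 to 10.48.

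The homeobox genes Dlx5 and Dlx1, which direct the development of GABAergic neurons, had the largest falls of named rows after Vof16, by 1.01 and 0.87 on the log2 scale. They were followed by Gpc2 (-0.82 ± 0.072), a glypican of growing axons, Zbtb12 (-0.81 ± 0.089), Celsr3 (-0.74 ± 0.068), a cadherin needed for axon tracts, Nefm (-0.72 ± 0.079), a neurofilament subunit, and Snn (-0.71 ± 0.11). The vesicular GABA transporter Slc32a1 fell by 0.71. The remaining rows of the 15 lowest were Pnma8b (-0.70), Zfhx2 (-0.70), Pcdh1 (-0.69), N5 (-0.69), Sema4c (-0.68) and Apc2 (-0.68). Every LPS brain lay on the same side of the saline mean for each of these highest and lowest rows. With the erythroid level as a covariate 6 of these genes were no longer called, with changes of 0.21 for Ahsp, 0.18 for Rhag, 0.21 for Hbg1, -0.26 for Vof16, -0.26 for Snn and -0.32 for N5. Apold1 was then at 0.88 and Arrdc3 at 0.68, still called but below Lrrcc1 (1.08) and Chm (1.03); the meninges covariate put Hbg1 at 0.78.

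Of 29215 transcript rows, 14074 (48.2%) were called, 5760 higher and 8314 lower in LPS brains. After centring each array on its median the split was 7157 higher and 5356 lower, so which side was larger depended on the scaling. Changes of at least 1.5-fold were found in 1041 rows, 800 higher and 241 lower, and changes of at least 2-fold in 45, 33 higher and 12 lower; the median size among called rows was 1.2-fold. By gene, 7642 of 14506 were called, 3300 higher and 4342 lower. The groups did not overlap at all in 3876 rows, where chance gives 0.00217% of rows.

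**Figure D2:**
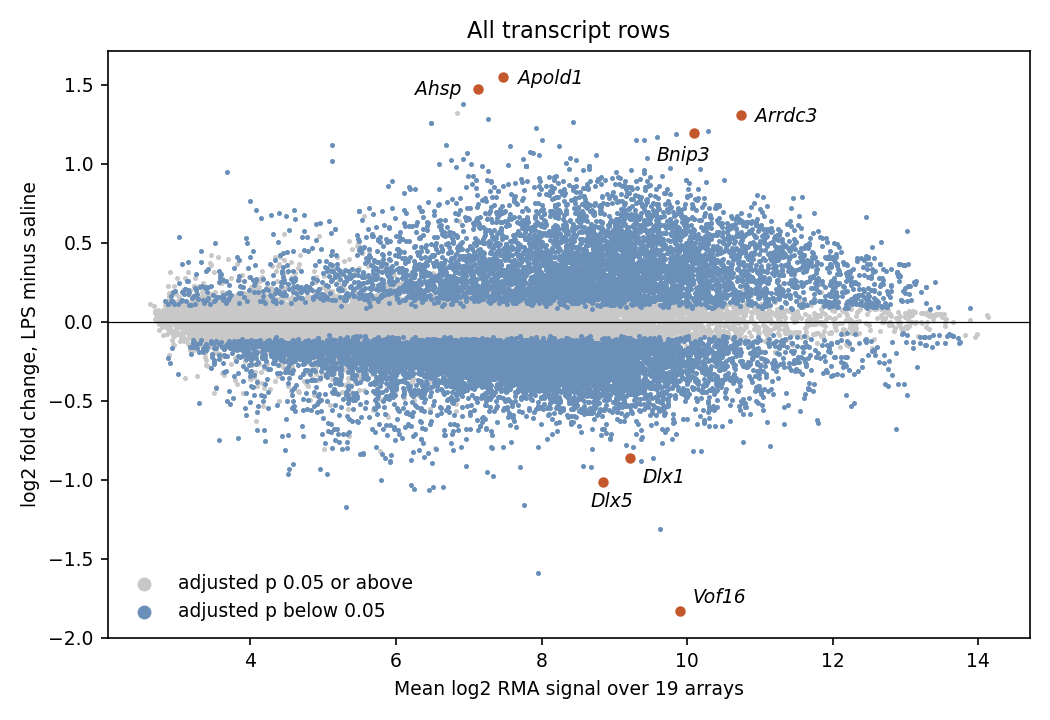
Log2 fold change (LPS minus saline) of each of 29215 transcript rows against its mean log2 RMA signal over the arrays, with rows at an adjusted p below 0.05 in blue, others in grey and some named genes in orange. Most called rows lie within 1.5-fold, and Apold1 (1.55), Vof16 (-1.83) and Dlx5 (-1.01) stand outside the bulk.

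Genes that specify GABAergic interneurons were lower in LPS brains. Of 17 measured members of the interneuron list, 12 fell and 2 rose (13 and 2 adjusted over the list alone). Dlx5 went from 9.33 ± 0.21 (SD, n = 10) to 8.32 ± 0.22 (SD, n = 9) and Dlx1 from 9.63 ± 0.15 to 8.77 ± 0.29. Lhx6, the factor that marks interneurons of the medial ganglionic eminence, fell by 0.56, and the GABA-synthesising enzyme Gad1 fell by 0.53. The members that rose were Npy (0.42), a neuropeptide, and Zeb2 (0.26), a repressor needed for interneuron migration; both were named after their values were seen. The list had a median of -0.29 (camera adjusted p = 0.00534). The adjusted p = 0.74 with an estimated correlation. The median was -0.28 with the erythroid level as a covariate (adjusted p = 0.0591).

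General markers of postmitotic neurons were lower too, though not uniformly. Of 18 measured members, 12 fell and 3 rose (12 and 5 adjusted over the list alone). The neurofilament genes Nefm (-0.72) and Nefl (-0.55) and the RNA-binding protein gene Elavl3 (-0.63) fell, while Scg2, a granin of secretory granules, rose by 0.74. The median was -0.30 (camera adjusted p = 0.047). The call was lost with an estimated correlation (adjusted p = 0.876 with an estimated correlation), with either cell level as a covariate (median -0.27 and adjusted p = 0.213 for erythroid, -0.31 and 0.0558 for meninges), with dim rows removed (0.0575) and on leaving out saline replicate 1, 4, 7 or 10 or LPS replicate 4, 5 or 7 alone, to at most 0.0653 without saline replicate 1.

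Genes of neuronal migration and guidance moved in opposite directions. Of 25 measured, 9 rose and 8 fell (9 and 9 adjusted over the list alone). The chemokine receptors Ackr3 (0.75 ± 0.056) and Cxcr4 (0.58 ± 0.066), which guide tangentially migrating interneurons along Cxcl12, rose, as did the repellent Sema3a (0.58 ± 0.067), and the semaphorin receptor Plxna2 fell by 0.64. The list as a whole had a median of 0.0078 (camera adjusted p = 0.704). That median lay at percentile 48.28 among 10000 random lists matched on mean level. Over all 14506 genes 3300 rose and 4342 fell, so calls in both directions are not particular to this list. Cxcr4 was at 0.29 with the erythroid covariate and still called. In the excitatory lineage 3 of 10 genes rose and 3 fell: Slc17a6 (0.38) and Neurod6 (0.36) were higher and Pou3f2 (-0.43) and Neurod2 (-0.37) lower (camera adjusted p = 0.883; median 0.07, mean -0.0080). Neurod2 was not called with the erythroid covariate (-0.27, adjusted p = 0.135).

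**Figure D3:**
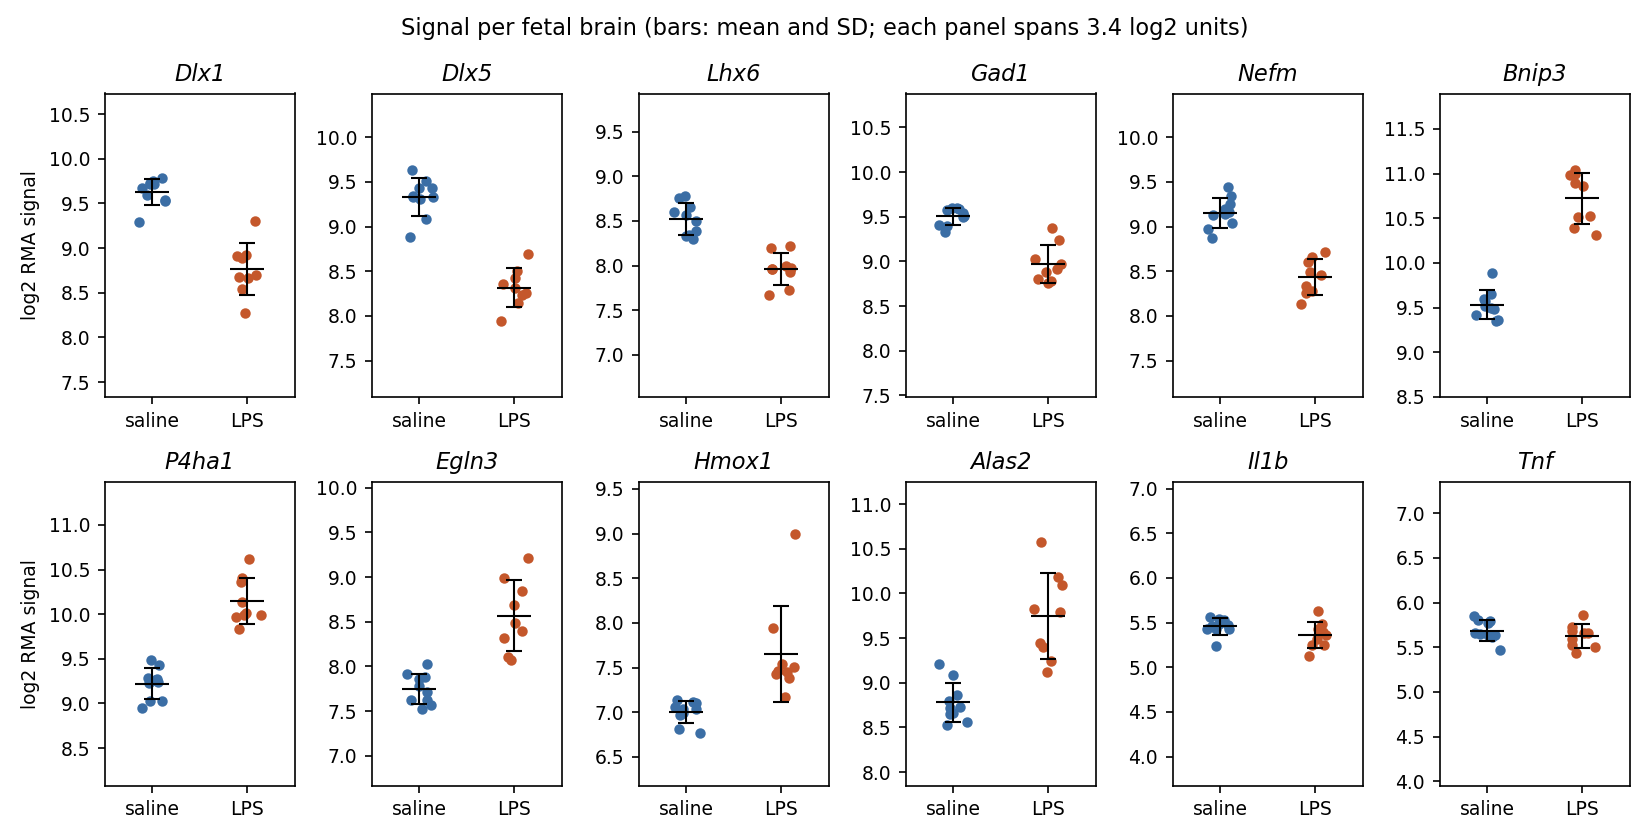
Log2 RMA signal of 12 genes in each fetal brain, with saline in blue (n = 10), LPS in orange (n = 9) and bars for mean and SD. Dlx5 has means of 9.33 and 8.32 and Bnip3 of 9.53 and 10.7, while the groups overlap for Il1b and Tnf.

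Antioxidant genes and targets of the stress factor NRF2 were mostly higher after LPS. Of 31 measured, 16 rose and 4 fell (19 and 4 adjusted over the list alone). The gene of NRF2 itself, Nfe2l2, rose by 0.77 ± 0.068 on the log2 scale, the peroxiredoxin gene Prdx4 by 0.65 ± 0.058, the haem oxygenase gene Hmox1 by 0.65 ± 0.16 and the glutathione transferase gene Gsta4 by 0.63 ± 0.064. Smaller rises were found for Nqo1 (0.32), Gclc (0.24) and Sod2 (0.21). The list had a median of 0.21 (camera adjusted p = 0.00184; adjusted p = 0.74 with an estimated correlation). With the erythroid level as a covariate the median was 0.087 (adjusted p = 0.12) and 4 of these genes were no longer called. Nfe2l2 was then at 0.50 and still called, Hmox1 at 0.091, Sod2 at 0.12, Gclc at 0.18 and Nqo1 at 0.28; with the meninges covariate Hmox1 (0.56) and Nqo1 (0.27) were not called.

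In the metal list 4 of 14 genes rose and 5 fell. Those that rose were the metallothioneins Mt1 (0.80 ± 0.20) and Mt2A (0.51 ± 0.11), the transferrin receptor Tfrc (0.69 ± 0.050) and the zinc importer Slc39a10 (0.38 ± 0.043). The median was -0.0043 and the mean 0.099, and the list was not called (camera adjusted p = 0.704). With the erythroid level as a covariate Mt1 changed sign, to -0.25 (adjusted p = 0.269), and Mt2A was no longer called (0.041, adjusted p = 0.853); with the meninges covariate Mt1 was not called (0.62, adjusted p = 0.0869).

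Transcripts of the classical inflammatory cytokines were not called higher in the fetal brain. Il6 differed by -0.0080 ± 0.066, Tnf by -0.061 ± 0.056 and Il1b by -0.099 ± 0.056, with adjusted p of 0.933, 0.387 and 0.147; without LPS replicate 7, Il1b was called lower (adjusted p = 0.0374). Of 26 cytokines and chemokines measured, 3 rose and 3 fell. Il18 (0.57 ± 0.087), Ccl3 (0.42 ± 0.11) and Ccl2 (0.25 ± 0.065) rose, and the interferon genes Ifnb1 (-0.31 ± 0.073) and Ifng (-0.27 ± 0.082) were among those that fell. Ifng was not called after quantile normalization (adjusted p = 0.0604), and 3 others of these lost their calls with the erythroid covariate, at 0.19 for Ccl2, 0.032 for Ccl3 and -0.26 for Ifnb1, while Il18 was at 0.36 and still called. With the meninges covariate Ccl2 (0.14), Ccl3 (0.34), Ifnb1 (-0.23) and Ifng (-0.20) were not called. The list had a median of -0.066 (camera adjusted p = 0.704). Of its 26 genes 9 had a saline mean of at least 6, so small changes of dim cytokines are not excluded. Il18 (saline mean 4.47), Ccl3 (5.79), Ifnb1 (5.54) and Ifng (5.10) were themselves below 6. Rows at a mean level of 4 to 6 were in general called lower (1622) more often than higher (360).

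Among targets of NF-kB 7 of 24 rose and 2 fell, led by the adhesion molecule Vcam1 (0.91 ± 0.062), with Ier3 (0.37), the LPS co-receptor Cd14 (0.33) and the LPS receptor Tlr4 (0.32). The median was -0.064 and the mean 0.043 (camera adjusted p = 0.704). Of 22 interferon response genes 1 rose and 3 fell (1 and 0 adjusted over the list alone). B2m, the light chain of class I antigen-presenting molecules, rose by 0.71 ± 0.11, and Mx2 (-0.62 ± 0.20), Isg15 (-0.17) and Ifit2 (-0.15) fell. With the erythroid covariate B2m (0.39), Mx2 (-0.34), Ifit2 (-0.060), Ier3 (0.13), Cd14 (0.38) and Tlr4 (0.23) were no longer called. Cd14 lost its call although its change was no smaller than the 0.33 without the covariate. With the meninges covariate Mx2 (-0.69), Ifit2 (-0.19), Ier3 (0.16), Cd14 (0.27) and Tlr4 (0.15) were not called. Isg15 and Ifit2 were not called after quantile normalization or median centring, although Isg15 was lower and called with the erythroid (-0.25, adjusted p = 0.0481) and meninges (-0.26, adjusted p = 0.00761) covariates, and Mx2 was not called by the exact Wilcoxon test (adjusted p = 0.137). The interferon list had a median of -0.018 and a mean of -0.0030, while camera put it on the upper side (adjusted p = 0.788).

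Genes induced by low oxygen rose together. Of 33 measured, 24 rose and 2 fell, with a median of 0.34. Besides Bnip3 these were led by the prolyl hydroxylase genes P4ha1 (0.92 ± 0.092) and Egln3 (0.82 ± 0.12) and the clock repressor Bhlhe40 (0.87 ± 0.15). The angiogenic factor Vegfa rose by 0.37 ± 0.12, but was not called by the exact Wilcoxon test (adjusted p = 0.0701) or without LPS replicate 1 and saline replicate 8 (0.0541). The list was called by camera (adjusted p = 1.41e-05; adjusted p = 0.74 with an estimated correlation). With the erythroid level as a covariate the median dropped to 0.06 (adjusted p = 0.02), and Bhlhe40 (0.23), Egln3 (0.49) and Vegfa (0.065) were no longer called; with the meninges covariate the median was 0.16 (adjusted p = 0.0044) and Vegfa, at 0.12, was not called.

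Red cell transcripts were higher in LPS brains at the same time. Of 17 erythroid genes 12 rose and 0 fell, with a median of 0.52 (camera adjusted p = 0.0013; adjusted p = 0.814 with an estimated correlation). The median was 0.33 with the meninges covariate (adjusted p = 0.012). Alas2, the enzyme that starts haem synthesis in red cells, rose by 0.96 ± 0.15, beside Ahsp, Rhag and Hbg1. Alas2 was not called with the erythroid covariate (0.11, adjusted p = 0.279), which holds its own level. The erythroid level was 8.07 ± 0.098 (SD, n = 10) in saline and 8.58 ± 0.30 (SD, n = 9) in LPS brains.

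The mitochondrial respiratory chain was higher: of 29 genes 20 rose and 5 fell (21 and 6 adjusted over the list alone). Ndufa1 (0.69 ± 0.077), Cox7a2 (0.59 ± 0.053), Sdhd (0.57 ± 0.048) and Atp5po (0.52 ± 0.061), from 4 of the complexes, had the largest changes. The median was 0.25 (camera adjusted p = 1.08e-05; adjusted p = 0.74 with an estimated correlation). Cell cycle genes were also higher, with 14 of 27 rising and 1 falling (15 and 1 adjusted over the list alone). The mitotic kinases Bub1 (0.81 ± 0.069) and Cdk1 (0.66 ± 0.072) and the cyclins Ccne2 (0.76 ± 0.069) and Ccnb2 (0.55 ± 0.053) led this list, which had a median of 0.12 (camera adjusted p = 0.000856). That call was lost with an estimated correlation (adjusted p = 0.876 with an estimated correlation) and with the erythroid covariate (median 0.083, adjusted p = 0.101), where Cdk1 was at 0.40 and still called. Among 10000 random lists matched on mean level the cell cycle median lay at percentile 81.05, inside their usual range.

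**Figure D4:**
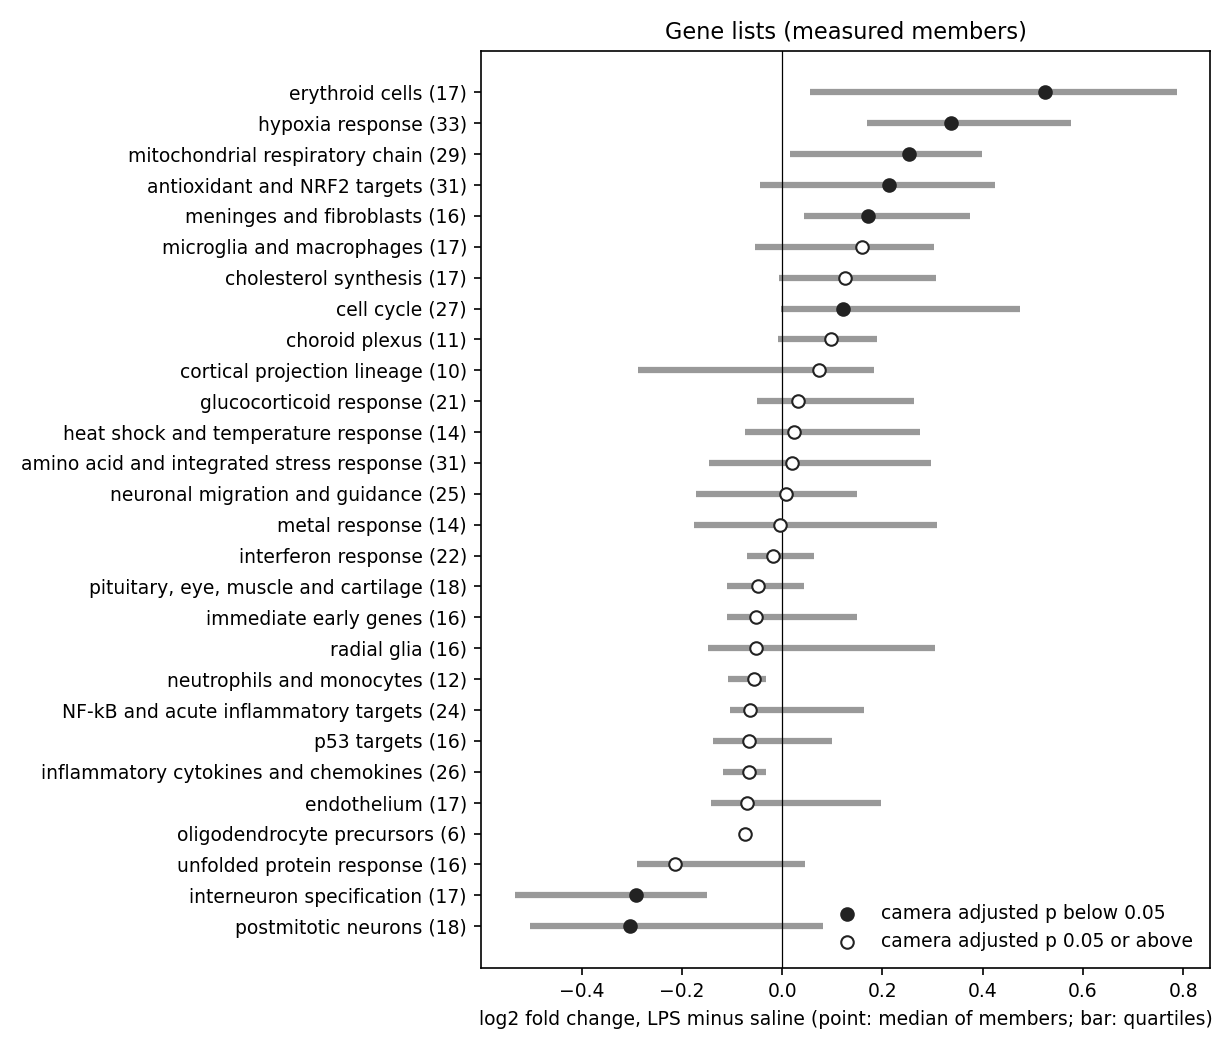
Median log2 fold change (LPS minus saline) of the members of each gene list, with bars from the lower to the upper quartile, numbers of measured members in parentheses and filled points for a camera adjusted p below 0.05. Erythroid (0.52) and hypoxia (0.34) genes stand at the top and interneuron (-0.29) and postmitotic neuron genes (-0.30) at the bottom.

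Stress programmes other than hypoxia were mixed. In the unfolded protein response 9 of 16 genes fell and 3 rose (10 and 3 adjusted over the list alone). The chaperones Hyou1 (-0.48) and Hspa5 (-0.39) and the ubiquitin ligase Syvn1 (-0.43) fell and the translocon subunit Sec61b rose by 0.44; the list had a median of -0.21 (camera adjusted p = 0.294) and was called after quantile normalization (0.0357). Hspa5 was not called with the meninges covariate (-0.30, adjusted p = 0.116). Of 31 amino acid and integrated stress genes 10 rose and 8 fell (12 and 8 adjusted over the list alone). Ddit4 (0.58), Vldlr (0.55) and the serine synthesis enzyme Phgdh (0.47) rose and the arginine transporter Slc7a1 (-0.55) fell (median 0.019, camera adjusted p = 0.704). Of 14 heat shock genes 6 rose and 4 fell, with rises of Chordc1 (0.52), the cold-inducible Rbm3 (0.43), Hspe1 (0.41) and Hspa4l (0.29) (median 0.025, camera adjusted p = 0.317).

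Of 21 glucocorticoid-responsive genes 8 rose and 3 fell; Arrdc3, Mt1, Ddit4 and Mt2A had the largest rises and Fkbp5, a classical target of the receptor, fell by 0.40 (median 0.032, camera adjusted p = 0.275). Of 16 immediate early genes 3 rose and 3 fell, among them Nr4a1 (0.43), Fos (0.35), Egr1 (0.32) and Klf2 (-0.33). Their median was -0.052 and their mean 0.013 (camera adjusted p = 0.96). Fos was higher than the saline mean in 6 of 9 LPS brains and was not called by the exact Wilcoxon test (adjusted p = 0.137). Of 16 p53 targets 2 rose, Fas (0.21) and Plk2 (0.20), and 5 fell, among them Zmat3 (-0.29) and Phlda3 (-0.17) (median -0.066, camera adjusted p = 0.788). Plk2 and Phlda3 were not called after quantile normalization. In cholesterol synthesis 9 of 17 genes rose and 4 fell, led by Nsdhl (0.58), Idi1 (0.46), Msmo1 (0.43) and Hsd17b7 (0.37) (median 0.13, camera adjusted p = 0.116). Ddit4 and Fos changed sign with the erythroid covariate, to -0.11 and -0.18, and Nr4a1 (0.011), Egr1 (0.098), Fas (0.14), Plk2 (0.099) and Phlda3 (-0.23) were no longer called, while Phgdh was at 0.25 and still called. With the meninges covariate Ddit4 (0.41), Nr4a1 (0.35), Fos (0.26), Egr1 (0.20) and Plk2 (0.14) were not called.

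Among the cell type lists, fibroblast and meningeal genes were higher, with 5 of 16 rising and 1 falling. The matrix genes Ogn (0.96 ± 0.13), Lum (0.90 ± 0.11), Dcn (0.87 ± 0.12) and Postn (0.79 ± 0.072) accounted for most of this. The median was 0.17 (camera adjusted p = 0.0279; adjusted p = 0.876 with an estimated correlation). The call was also lost with array weights (0.0559), with dim rows removed (0.11), with the erythroid covariate (median 0.040, adjusted p = 0.401), and without saline replicate 1 (0.0523) or LPS replicate 7 (0.0585), as well as without LPS replicate 1 and saline replicate 8 together (0.0547). With the meninges covariate, which holds their own levels, Ogn was at 0.56, Lum at 0.54 and Dcn at 0.49.

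Of 17 microglia and macrophage genes 8 rose and 1 fell, led by the mannose receptor Mrc1 (0.62 ± 0.10), the complement gene C1qc (0.55 ± 0.061), P2ry12 (0.42) and Ptprc (0.40). The median was 0.16 (camera adjusted p = 0.0564), and the list was called after quantile normalization (0.0118). It was also called without saline replicate 8 (0.0467), LPS replicate 3 (0.0336) or LPS replicate 8 (0.0417). Its median was 0.060 with the meninges covariate (adjusted p = 0.256), where Mrc1 was at 0.26 and Ptprc at 0.25, and 0.099 with the erythroid covariate (adjusted p = 0.097). Neutrophil and monocyte genes showed 0 rises and 2 falls among 12, in Camp (-0.33) and Elane (-0.26) (median -0.055, camera adjusted p = 0.611). Neither was called with the erythroid covariate (-0.29 and -0.14) or the meninges covariate (-0.20 and -0.13). Of the 12 neutrophil and monocyte genes 3 had a saline mean of at least 6. Random lists matched on mean level had a median of -0.073, so by its median this list was no lower than other genes of its level.

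Radial glia genes had 6 rises and 3 falls among 16. Hes1 (0.53), Prom1 (0.42), Fabp7 (0.37) and Hopx (0.32) rose, and the list had a median of -0.053 but a mean of 0.056 (camera adjusted p = 0.704); with the erythroid covariate Hes1 changed sign, to -0.28. Of 6 oligodendrocyte precursor genes Pdgfra rose by 0.38 and Cspg4 fell by 0.23 (median -0.073, camera adjusted p = 0.788). Of 17 endothelial genes 5 rose and 1 fell (4 and 1 adjusted over the list alone), with Emcn (0.59), Pecam1 (0.37) and Esm1 (0.29) higher and the tight junction gene Cldn5 (-0.27) lower (median -0.070, mean 0.037, camera adjusted p = 0.704). Choroid plexus genes had 2 rises among 11, Enpp2 (0.69) and Sostdc1 (0.36) (median 0.098, camera adjusted p = 0.275). Genes of pituitary, eye, muscle and cartilage had 1 rise, Tyrp1 (0.25), and 5 falls among 18 (1 and 3 adjusted over the list alone), with Matn1 (-0.22), Lhx3 (-0.18, not called after quantile normalization) and Crybb1 (-0.16) lower (median -0.047, camera adjusted p = 0.788). With the erythroid covariate Pdgfra (0.33), Cspg4 (-0.28), Pecam1 (0.19), Esm1 (0.18), Cldn5 (-0.24), Sostdc1 (0.15), Tyrp1 (0.20), Matn1 (-0.12), Lhx3 (-0.25) and Crybb1 (-0.11) were no longer called. With the meninges covariate Cspg4 was called at -0.38 (adjusted p = 0.0011), Pdgfra was at 0.036, and Hes1 (0.48), Pecam1 (0.18), Esm1 (0.27), Sostdc1 (0.33), Matn1 (-0.14), Lhx3 (-0.17) and Crybb1 (-0.15) were not called either. For the lists with no separate count, adjustment over the list alone gave the same counts.

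In all, camera called 8 of 28 lists, 6 higher and 2 lower, and 0 with an estimated correlation. Other splits of the same brains into 10 and 9 often called as many lists, 22 of 100 with the real split counted. An exact permutation test of list levels, chosen after seeing the data, which asks whether a list differs between groups and does not set it against other genes, called 15. Those were the 8 lists, with the metal, glucocorticoid, heat shock, cholesterol and microglia lists higher and the unfolded protein and neutrophil lists lower. The cytokine list was not called (adjusted p = 0.145). In the screen of gene families this test also called many families, such as Or (adjusted p = 0.00106) and Klf (5.74e-05), but not Il (0.6). A call by it is thus not particular to a list. Medians of the metal (percentile 56.48), glucocorticoid (86.44), heat shock (40.42), cholesterol (76.81) and neutrophil (70.61) lists lay inside the usual range of random matched lists.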

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

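Among 330 sets of group values, from the named genes, the list levels and the array measures, 22 (6.67%) held a brain far from the rest of its group, where chance gives about 5%. Saline replicate 6 stood apart most often. It had the highest saline signal of Apold1, 7.66 against 6.47 to 6.97 in the other saline brains, and of the red cell gene Rhag, 6.37 against 5.58 to 5.94 in each of a pair of identical rows. It was also highest for the early gene Nr4a1 (6.24), for the choroid plexus gene Sostdc1 (7.63), for the mean level of the hypoxia list (9.19 against 8.96 to 9.07) and for that of the erythroid list (8.31 against 7.97 to 8.14), and lowest for the radial glia gene Fabp7 (12.02 against 12.21 to 12.41).

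Saline replicate 8 was lowest for B2m (8.95 against 9.45 to 9.85), for the endothelial gene Pecam1 (6.69) and for the level of the glucocorticoid list (7.90). Cd14 was highest in saline replicate 2 (7.34 against 6.83 to 7.08), and Il1b was lowest in saline replicate 7 (5.23 against 5.43 to 5.56).

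LPS replicate 1 lay nearest the saline side for the axonal genes Gpc2 (10.1 against 9.40 to 9.71 in the other LPS brains) and Sema4c (8.80), for the cholesterol gene Idi1 (10.06 against 10.25 to 10.43) and for the respiratory chain gene Sdhd (10.04 against 10.3 to 10.43). Hmox1 was highest in LPS replicate 8, at 8.99 against 7.17 to 7.94. LPS replicate 7 had the highest Ier3 (7.46 against 6.65 to 6.86) and the lowest Elane (5.69). The interferon gene Mx2 was highest in LPS replicate 9, at 6.63 against 5.33 to 5.70, and the precursor gene Cspg4 lowest in LPS replicate 3, at 6.02 against 6.41 to 6.70.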

How the results depend on the processing

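Limma treat at 1.2-fold, the removal of identical rows, the fit without LPS replicate 1 and saline replicate 8 and the exact permutation of list levels were chosen after seeing the data. The called transcripts numbered 12692 after quantile normalization (11202 of them shared with the 14074), 13491 by the exact Wilcoxon test, 13454 without LPS replicate 1 and saline replicate 8, and 13230 to 14295 on leaving out each brain in turn. Rows with 1 symbol gave 8401 (3713 higher, 4688 lower), as fewer rows were tested. Median centring left 5356 lower. The erythroid covariate gave 7346 (3693 higher, 3653 lower) and the meninges covariate 5365 lower; the cause was not tested. Thresholds of 1.2-fold gave 7018 (3720 higher, 3298 lower), 1.5-fold 1041 (800 and 241), and limma treat 2344 (1723 and 621), by their construction.

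Of the 8 lists called, 2 lower, 1 was lower with a mean log2 of at least 6 and with the meninges covariate, and 1 to 2 on leaving out each brain in turn. The erythroid covariate called 2 lists, 2 higher and 0 lower. With it the interneuron median was -0.28 (adjusted p = 0.0591) and the antioxidant median 0.087 (0.12), and the erythroid list (-0.038), Mt1 (-0.25), Ddit4 (-0.11), Fos (-0.18) and Hes1 (-0.28) reversed; the erythroid list is centred by its own level, as is the meninges list (-0.093) with the meninges covariate. The causes of the others were not tested. Over all alternatives the adjusted p of the interneuron list ran from 1.62e-05 by fry to 0.74 by camera with an estimated correlation. For the antioxidant and hypoxia lists it ran up to 0.74. Fry asks whether a list differs between groups and does not set it against other genes, so these ends answer different questions. The estimated correlation called 0 lists (0 higher, 0 lower), with the medians of interneuron (-0.29), antioxidant (0.21) and hypoxia (0.34) genes unchanged by its construction. Fry called 15 (10 higher, 5 lower) and the exact permutation of list levels 15 (11 higher, 4 lower), with the metal list at 0.099, since it takes the mean and not the median. Of 134 named rows, 43 lost their call and 4 reversed with the erythroid covariate, and 29 lost it with the meninges covariate. Of rows still called, 7 were smaller by over 1.5 times with the erythroid and 6 with the meninges covariate. The erythroid level follows the group (r = 0.784), and the SE of the interneuron level difference was 0.041 without and 0.066 with it. A lost call alone thus does not show a smaller change. On leaving out a single brain, Ifit2 lost its call in 11 fits (adjusted p to 0.091 without LPS replicate 2), and Il1b was called without LPS replicate 7 (-0.13, adjusted p = 0.0374).

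No clear pairing by replicate number was found. Deviations of same-numbered brains correlated over 0.1 in 2 of 9 pairs (-0.086 to 0.19, median 0.075), and 1 LPS brain correlated best with its own number. These correlations were not set against other pairs by a test, so a weak tie by number is not excluded. With the replicate block 12999 transcripts were called, 5505 higher and 7494 lower, and 9 lists. Of the named rows 3 lost their call with it, and 1 list gained a call. The covariate for fetal sex was not run.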

Other observations

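The screen of gene families, the random lists matched on mean level, the tests of neuron number and developmental stage, the erythroid-adjusted list levels, the erythroid and hypoxia correlations, and the test of spread between brains were chosen only after the results were seen. Grouped by shared symbol stem, 106 families of genes were screened with limma camera, of which 12 were higher and 5 lower. Of 43 genes with the ribosomal protein stem Rpl, 37 rose and 0 fell (median 0.28, adjusted p = 3.18e-13; adjusted p = 0.671 with an estimated correlation), and 0 of the 106 families were called with an estimated correlation. Bright transcripts were higher in general, with a median of 0.11 over rows at a mean level of 10 to 12 and 0.093 at 12 to 15, where Rpl genes lie. Likewise 23 of 33 Rps genes rose (0.32) and 30 of 41 mitochondrial ribosome genes (Mrpl) rose (0.31), while of 44 translation factor genes (Eif) 23 rose and 10 fell (0.16). Complex I genes (Nduf) had 30 rises among 37 (0.32), intraflagellar transport genes (Ift) 12 among 17 (0.25) and centrosomal Cep genes 14 among 22 (0.25). Calcium channel genes (Cacn) fell in 16 of 24 (-0.34), Map genes in 25 of 37 (-0.22) and Trim genes in 25 of 43 (-0.17). These medians kept their sign after quantile normalization, at 0.14 for Rpl, and 0.068 for Eif, and after median centring. Of 1052 olfactory receptor genes (Or), dim at a median level of 4.23, 9 rose and 181 fell (median -0.062, and -0.0061 after median centring; adjusted p = 0.108).

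The breadth of the difference is the pattern that most needs care. In the real split 14074 transcripts were called, against at most 1 in each of 99 other splits of the brains. Thus 1 of 100 splits drawn, out of 92378 possible, reached the real count, which argues against a chance division of single brains. The splits moved single brains, so they cannot speak to a chance division of dams or litters. Signal distributions left unequal by the normalization are argued against as the source of most calls. Quantile normalization still gave 12692, of which 11202 were shared with the 14074. Part of the pattern depended on them, as rows called lower went from 8314 to 6703 and rows called higher from 5760 to 5989. Blood in the tissue cannot be told apart from the treatment, because the erythroid level follows the group (r = 0.784) and taking it as a covariate left 7346. Regional base composition, a trace of RNA handling, labelling or array batch, stays open: fold changes of genes next to each other correlated at r = 0.183 over 8524 pairs, across genes that are not independent replicates, against at most 0.0355 in 1000 shuffles, and co-regulation of neighbours may give the same value. A batch that coincides with the groups, and litters that differ, could not be tested from the labels.

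The hypoxia genes were higher after LPS; the maternal treatment stays among the open explanations, as untested, since no measure of oxygen was analysed here. A general rise of bright transcripts is argued against, since the list median lay at percentile 100 of 10000 random lists of matched level, whose median was -0.0085. The genes of those lists were drawn independently, while hypoxia genes correlate (estimated at 0.36), so that percentile is too extreme. A change in a single brain is argued against too, since the highest camera adjusted p on leaving out each brain was 7.45e-05. A higher share of blood cells cannot be told apart from the maternal treatment. With the erythroid level as a covariate the list median was 0.060, and the level difference went from 0.36 ± 0.060 to 0.17 ± 0.080 (95% interval 0.0015 to 0.34). Of the 17 erythroid genes, 1 stands in another list and 16 had a saline mean of at least 6; within groups the erythroid and hypoxia levels correlated at r = 0.607 in saline (rho 0.212; permutation p = 0.087 and 0.558; r = -0.103 without the 2 farthest brains) and 0.603 in LPS (rho 0.567; exact permutation p = 0.0882 and 0.121; r = 0.395 without them), with an adjusted p of 0.118 for each r among 4 relations.

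The fall of interneuron and neuronal genes may be a change of transcription in these cells. That hypothesis was not tested, since arrays of brain tissue cannot tell expression per cell from the share of cells. Fewer neurons alone would not raise members of the list, yet 3 of 18 postmitotic neuron genes rose. Over all genes 3300 of 14506 rose, so these rises do not show what lowered the others. A smaller share of neurons therefore stays open. A general fall of transcripts of that level is argued against by the interneuron median, at percentile 0.02 of random matched lists, and the postmitotic median, at percentile 0.01. Those random lists had medians of -0.017 and 0.031. Their genes were drawn independently, while members of the real lists correlate (estimated at 0.24 and 0.39), so the percentiles are too extreme. An earlier stage of the LPS brains cannot be told apart from the treatment, because radial glia genes went both ways (adjusted p = 0.704). With the erythroid level as a covariate the interneuron level difference went from -0.32 ± 0.041 to -0.27 ± 0.066 (95% interval -0.41 to -0.13) while the camera call ended (adjusted p = 0.0591); why it ended was not tested.

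Camera called 8 lists in the real split and up to 11 in the others, with 22 of 100 splits calling as many, so chance is not excluded for that number of lists. Among random lists of matched level, the medians of the other called lists lay at percentile 100 for erythroid, 99.51 for antioxidant, 98.74 for respiratory chain, 98.58 for meninges and 81.05 for cell cycle genes. Of the lists camera did not call, microglia lay at percentile 100 and the unfolded protein response at 0.11, and the rest between 15.28 and 96.79. The random lists hold genes drawn independently, so for lists whose members correlate extreme percentiles overstate how rare such a median is. Hypoxia and interneuron levels did not correlate detectably within groups, with r = -0.0967 over the LPS brains (rho 0.233; exact permutation p = 0.808 and 0.552; r = 0.537 without the 2 farthest brains) and 0.588 over the saline brains (rho 0.588; permutation p = 0.073 and 0.0799; r = 0.521 without them), at adjusted p of 0.808 and 0.118. LPS brains lay farther from the rest of their group than saline brains, by 0.197 ± 0.022 (SD, n = 9) against 0.152 ± 0.019 (SD, n = 10) log2 units (two-sided exact permutation p = 0.00049). The permutation kept the distances as computed in the real groups. Distances within a group share brains and are not independent, so this p is approximate.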
